A study of Mus musculus with 12 samples.

How the data were processed

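Per the labels, the libraries were made from B16F10 cells with sgNC or sgRnf19a, untreated or 24 h into a treatment called IR, not spelled out. Per the labels' protocols, RNA was taken from cell pellets with a Qiagen RNeasy kit, ribosomal RNA was depleted, strand-marked libraries were made with an NEB Ultra Directional kit and 12 PCR cycles, and an Illumina NextSeq 500 read pairs of 37 bp. Per the submitters' processing notes, Bowtie2, HTSeq and DESeq2 and the builds mm10 and GRCm39 were used; versions, the role of each, and whether counting used strand are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain.

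The authors deposited a table of counts per Ensembl gene, not normalized, and a table of FPKM values, which per the file headers carry 1 column per library. The deposited counts are whole numbers, but low values of genes with transcripts over 2 kb piled up at multiples of 4: the value 4 occurred 5833 times, against 961 for 3 and 959 for 5. One read pair is thus worth about 4 counts, and the values were treated as estimated counts. Of 55401 genes, 29550.0 had a count. Coordinates are those of the FPKM table: of 29456 IDs shared with GENCODE M21, the annotation of mm10, 26714 had the same start and end. A further 12 per-sample columns that repeat the counts were not used.

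Untreated columns were matched to samples by genotype and number. The other 6 columns carry a D and no word for IR; they were placed in the IR-treated groups because the labels leave no other group for them, and their numbers (1, 4 and 5 for control, 1, 3 and 4 for sgRnf19a) are not those of the labels. Libraries of a group were compared pairwise, and every pair differed by more than counting noise, so none is a copy of another.

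Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), leaving 18183. Counts were scaled by TMM and fitted over all 12 libraries with 4 group means by edgeR's quasi-likelihood model (glmQLFit, robust, and glmQLFTest, 2-sided), in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. The 5 comparisons are IR in control cells, IR in sgRnf19a cells, the guide in untreated cells, the guide in IR-treated cells, and the difference between the 2 IR responses. CPM are TMM-scaled.

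Gene lists numbered 25: interferon-stimulated genes, nucleic acid sensing, MHC class I, NF-kB and cytokines, checkpoint ligands, ubiquitin pathway, p53 targets, replication, mitosis, DNA repair, histones, melanocyte pigmentation, stress responses, hypoxia, cholesterol, MAPK, extracellular matrix, proteasome, respiratory chain, lysosome, ribosomal proteins, mitochondrially encoded genes, and markers of fibroblasts, immune cells and endothelium or keratinocytes. Each was tested with camera (limma 3.58.1, correlation 0.01), with an estimated correlation and with fry, adjusted over all lists and comparisons. Camera calls of 11, 11, 10, 9 and 6 lists in the 5 comparisons came down to 0 in each with an estimated correlation. Fry called 15, 15, 8, 11 and 4 lists. The groups, comparisons, tests, lists, named-gene rule and all alternatives except 3 were set before the data were examined. The rule named, per comparison, Rnf19a, the 6 called genes with the largest log2 fold change in each direction (mean of at least 2 CPM, no overlap between libraries of the 2 groups, no predicted or unnamed genes), up to 4 members with the smallest p per described list, and 25 further fixed genes, changed or not.

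Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, no filter, 1 CPM in 3 libraries, a replicate block, only the 2 groups compared, an absolute log2 fold change of 1, limma on log2(FPKM + 1) with a mean of at least 0.5 FPKM, on log2(FPKM + 0.1) and without that filter, and leaving out each library. After the data were seen, a correction by splines (5 degrees of freedom) on transcript length and GC content per library, counts divided by 4 and a block on the column numbers of the IR-treated libraries were added. Fold changes on FPKM are on the log2(value + pseudocount) scale and understate low genes.

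The count test was tested on simulated data with 200 genes changed. For IR in control cells edgeR recovered 24 of 100 changed 2-fold and 83 of 100 changed 4-fold, calling 3 others of 17546 genes. For the difference between IR responses it recovered 4 and 59 of 100 each and called 4 others of 17401. In a simulation with the fitted length and GC trends, 200 genes were changed in the untreated sgRnf19a group. Of 17530.0 genes, 6116 were called for IR in control cells, 2455 for IR in sgRnf19a cells, 96 for the guide in untreated cells and 474 for the guide in IR-treated cells. After the correction the 4 counts were 0, 132, 133 and 0, of which 0, 6, 5 and 0 were genes that had not been changed. The simulated trends came from the same fit that the correction uses, so their removal was built in. The simulation does not test whether the correction removes other shifts between the real libraries. For the guide in untreated cells the corrected test recovered 37 of 100 genes changed 2-fold and 91 of 100 changed 4-fold. A floor of 3 read pairs, 12 counts over a group, was used for genes at 0; floors cover counting error only, since PCR copies without molecular identifiers are not independent. Transcript length and GC content came from GENCODE M21. The level of 1 gene of the intestinal list is not reported here. Figures were drawn with matplotlib 3.10.9.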

Results

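RNA-seq counts were analysed for 12 libraries in 4 groups of 3. The labels call the cells B16F10, a transplantable mouse melanoma line. The counts leave that identity open. The melanocyte genes Tyr, Tyrp1, Mlana and Slc45a2 had 0 counts in all 12 libraries, while Krt8 was at 351 CPM in control. The cells carried a control guide (sgNC, called control here) or a guide against Rnf19a (sgRnf19a), and were untreated or exposed for 24 h to a treatment that the labels call IR. Rnf19a encodes a RING-between-RING E3 ubiquitin ligase, and the labels call the sgRnf19a cells deficient in it. The series title places the work in the control of the ubiquitin pathway by the kinase RSK1 and in immune suppression. The comparisons ask what IR changed in each genotype, what the guide changed without and with IR, and where the IR response differed between genotypes. Total counts ran from 62.7 to 71.3 M in the 6 untreated libraries and from 34.3 to 45.6 M in the 6 IR-treated libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which can be technical. IR-treated libraries are named by the number in their column, which is not the replicate number of the labels. Levels are means ± SD over 3 libraries in CPM, counts scaled to the size of the library.

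The targeted gene, Rnf19a (ENSMUSG00000022280, mm10 chromosome 15, 36239933 to 36283147), was at 33.5, 29.4 and 21.5 CPM in control replicates 1, 2 and 3 and at 27.4, 25.6 and 22.6 CPM in sgRnf19a replicates 1, 2 and 3. With IR it was at 4.37, 8.06 and 5.39 CPM in control_IR replicates 1, 4 and 5 and at 18.1, 11.6 and 37.7 CPM in sgRnf19a_IR replicates 1, 3 and 4. The level in untreated sgRnf19a cells did not differ detectably from control (log2 fold change -0.16, SE 0.36, edgeR adjusted p = 0.881). A guide that shifts the reading frame need not lower the mRNA, so this level neither bears out nor contradicts the label. IR lowered Rnf19a 4.72-fold in control cells (log2 fold change -2.24, SE 0.38, edgeR adjusted p = 0.000521; -1.24 after a correction for transcript length and GC content), while in sgRnf19a cells its change did not pass (log2 fold change -0.16, SE 0.36, edgeR adjusted p = 0.766). Without sgRnf19a_IR replicate 4 it passed as a fall (log2 fold change -0.77, edgeR adjusted p = 0.0343). Among IR-treated cells it was 3.78-fold higher with the guide (log2 fold change 1.92, SE 0.38, edgeR adjusted p = 0.00352; 1.11 after that correction and 1.32 without the same replicate 4). The difference between the 2 IR responses did not pass (log2 fold change 2.08, SE 0.52, edgeR adjusted p = 0.0877), though it did with DESeq2, after that correction and without sgRnf19a_IR replicate 3 or 4.

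The IR-treated libraries differed from the untreated ones in the kinds of RNA they held. Counts in ribosomal RNA genes took 0.223% to 0.696% of each untreated library and 11.3% to 22.1% of each IR-treated library. The median log2 level of protein-coding transcripts over 6 kb minus that of transcripts under 1 kb was 1.12 ± 0.42 in control, 1.67 ± 0.10 in sgRnf19a, -1.86 ± 0.16 in control_IR and -0.69 ± 0.90 in sgRnf19a_IR. Across 10051 protein-coding genes, Spearman's rho between log2 fold change and transcript length was -0.614 for IR in control cells, -0.599 for IR in sgRnf19a cells and 0.371 for the guide in IR-treated cells; genes are not independent replicates. With GC content it was 0.533, 0.275 and -0.654. For the guide in untreated cells rho was 0.289 with length and -0.306 with GC content, and for the difference between IR responses 0.317 and -0.674. The first principal component held 46.9% of the variance. On it sgRnf19a_IR replicate 4 lay at -42.1, on the side of the untreated libraries, and sgRnf19a_IR replicates 1 and 3 at 51.0 and 86.7. The long-minus-short value of that replicate 4 was 0.20.

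**Figure D1:**
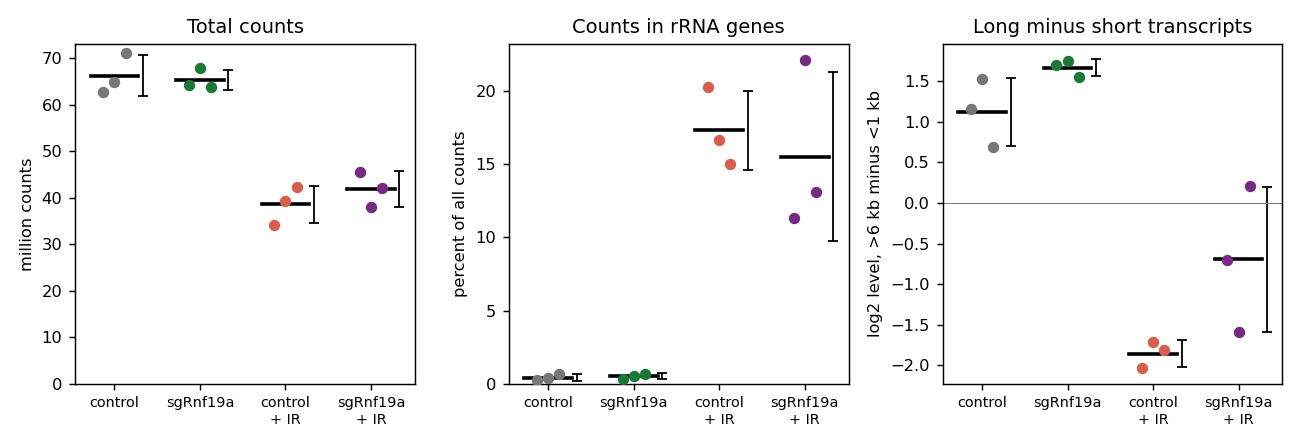
Total counts in M, percent of counts in ribosomal RNA genes, and median log2 level of transcripts over 6 kb minus that under 1 kb, per library in the 4 groups (points, libraries; line, mean; bar, SD, n = 3). The rRNA gene share of the IR-treated libraries starts at 11.3%, above the 0.696% of the highest untreated library.

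**Figure D2:**
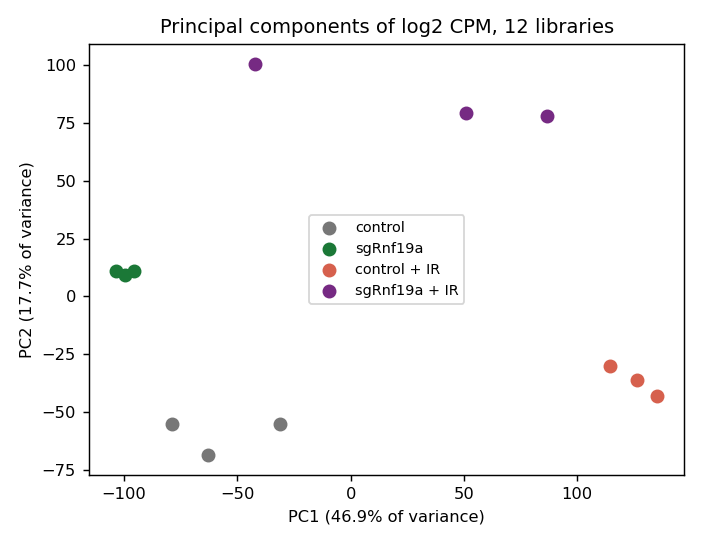
First and second principal components of log2 CPM for the 12 libraries, 1 point each, coloured by group, with the percent of variance on each axis. The sgRnf19a_IR point at -42.1 on the first component is replicate 4.

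In control cells IR raised genes of the interferon and chemokine response. Ifnb1, which encodes interferon beta, went from 0.194 ± 0.0472 CPM to 21.1 ± 4.19 CPM, 108-fold higher (log2 fold change 6.75, SE 0.36, edgeR adjusted p = 1.68e-06, n = 3 per group). The chemokine genes Cxcl11 and Cxcl10 rose 58.5-fold (log2 fold change 5.87, SE 0.32) and 39.8-fold (log2 fold change 5.31, SE 0.25). Of 65 interferon-stimulated genes tested, 42 rose and 2 fell (43 and 5 adjusted over the list alone). Isg15, a ubiquitin-like protein gene, was 13.0-fold, Ifit1 10.2-fold, Usp18 7.35-fold and Rtp4 8.18-fold higher. That list had camera adjusted p = 2.78e-11, adjusted p = 0.400 with an estimated correlation. Cgas, the cytosolic DNA sensor gene, fell 2.65-fold (log2 fold change -1.41, SE 0.32, edgeR adjusted p = 0.00333). After a correction for transcript length and GC content that fall was no longer called (log2 fold change -0.57, edgeR adjusted p = 0.191), nor was it on FPKM with no filter.

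Further groups rose or fell with IR in control cells. Of 24 MHC class I and antigen processing genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.00713, adjusted p = 0.486 with an estimated correlation). Tap1, a peptide transporter gene, rose 2.99-fold and Psmb8 2.44-fold, while the chaperone gene Pdia3 fell 3.04-fold. NF-kB targets, cytokines and chemokines gave 40 tested genes, of which 21 rose and 1 fell (21 and 4 adjusted over the list alone), among them Ccl5 10.6-fold, Cxcl1 4.86-fold and Ccrl2 10.5-fold higher (camera adjusted p = 0.000564, adjusted p = 0.462 with an estimated correlation). Among 33 MAPK pathway and immediate early genes 18 rose and 4 fell (18 and 4 adjusted over the list alone), including Atf3 11.3-fold and Jun 10.8-fold higher (camera adjusted p = 0.00240, adjusted p = 0.679 with an estimated correlation). Cholesterol synthesis genes were 27, and 18 rose and 4 fell (18 and 5 adjusted over the list alone), with Fdft1 2.79-fold and Msmo1 2.91-fold higher (camera adjusted p = 0.000215, adjusted p = 0.462 with an estimated correlation). Among 40 mitosis genes 6 rose and 26 fell (6 and 26 adjusted over the list alone; camera adjusted p = 0.000803, adjusted p = 0.434 with an estimated correlation). The proliferation marker Mki67 fell 23.6-fold and Tpx2 6.35-fold, whereas Pttg1 rose 2.88-fold. Among 36 DNA repair genes 1 rose and 29 fell (1 and 30 adjusted over the list alone), with Topbp1 9.28-fold and Trp53bp1 4.11-fold lower (camera adjusted p = 1.23e-07, adjusted p = 0.486 with an estimated correlation). The p53 target genes, 39 in number, moved both ways: 14 rose and 11 fell (15 and 12 adjusted over the list alone; camera adjusted p = 0.414). Btg2 was 2.76-fold and Gdf15 5.08-fold higher and Apaf1 3.63-fold and Mdm2 2.84-fold lower. On the FPKM scale 10 and 14 of them rose and fell. Corrected for length and GC content, the genes called higher and lower in each list, with those of them called the same way before (kept) and the list's median log2 fold change, were 49 and 1 (37 and 1 kept, 1.41) for interferon-stimulated, 9 and 5 (8 and 3 kept, 0.19) for MHC class I, 20 and 2 (19 and 0 kept, 0.59) for NF-kB, 14 and 4 (12 and 2 kept, 0.44) for MAPK, 21 and 0 (16 and 0 kept, 0.62) for cholesterol, 5 and 30 (4 and 25 kept, -0.97) for mitosis, 3 and 21 (0 and 20 kept, -0.80) for DNA repair and 15 and 8 (10 and 6 kept, 0.21) for p53 target genes. Of the MHC class I genes, 8 of 15 rises and 3 of 4 falls were still called.

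Short and untailed RNAs rose alongside the shift in rRNA share and transcript length. Of 59 replication-dependent histone genes, whose copies share reads and are uncertain one by one, 53 rose and 0 fell (57 and 0 adjusted over the list alone), and the list median was 3.27 on the log2 scale (camera adjusted p = 1.39e-19, adjusted p = 0.243 with an estimated correlation). Of 85 cytosolic ribosomal protein genes 78 rose and 0 fell (80 and 1 adjusted over the list alone; camera adjusted p = 8.96e-23, adjusted p = 0.486 with an estimated correlation). Nuclear respiratory chain genes numbered 34, and 31 rose and 2 fell (31 and 2 adjusted over the list alone; camera adjusted p = 6.55e-10, adjusted p = 0.535 with an estimated correlation). Proteasome genes numbered 31, and 21 rose and 2 fell (21 and 3 adjusted over the list alone; camera adjusted p = 0.000124, adjusted p = 0.623 with an estimated correlation). After the correction the genes called higher and lower, with those kept and the median, were 35 and 0 (33 and 0 kept, 1.56) for histone, 51 and 13 (50 and 0 kept, 0.51) for ribosomal protein, 17 and 10 (17 and 2 kept, 0.29) for respiratory chain and 13 and 9 (13 and 2 kept, 0.06) for proteasome genes. The near-identical 7SL RNA genes Rn7s1 and Rn7s2 rose 55.7-fold and 55.2-fold and are uncertain, as is Lars2 (113-fold higher), which carries sequence resembling rRNA. Krt16, a keratin gene, had 919 counts in control_IR against 7 in control. The largest falls were those of Sytl5 (0 counts in control_IR, at least 47.3-fold lower against a floor of 12 counts over the group), Septin2 (40.5-fold lower, 1 of several gene IDs with this symbol and so uncertain), Zfp820 (29.3-fold), Zfp449 (24.6-fold), Kif20b (24.5-fold) and Mki67. For genes given above with a fold change for this comparison that the correction moved by over 1.5 times with the call kept, it gave these fold changes in the direction above: Cxcl10 23.9, Isg15 4.46, Ifit1 16.7, Usp18 4.87, Psmb8 1.33, Ccl5 3.17, Atf3 7.42, Mki67 6.57, Tpx2 3.95, Topbp1 4.28, Trp53bp1 1.40, Gdf15 2.44, Apaf1 1.34, Rn7s1 14.6, Rn7s2 14.3, Septin2 17.2, Zfp820 8.18, Zfp449 10.1 and Kif20b 5.51.

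By edgeR's quasi-likelihood test, IR in control cells raised 4028 and lowered 4679 of 18183 genes at an adjusted p under 0.05. The 3 and 3 libraries did not overlap for 62.1% of genes, where chance gives 10%. In simulated counts that carried the length and GC trends of these libraries and no change between these 2 groups, 6116 genes were called for this comparison and 0 after the length and GC correction. That 0 was built in, since the simulated trends came from the fit that the correction uses. It does not show that real calls left after the correction are free of the shift in RNA kinds. In the real counts 7961 were called after the correction, 5619 of them among the 8707 and 4934 in the same direction. On the deposited FPKM scale the split was 2115 higher and 6038 lower. The median of all genes shifted by -0.44 on the log2 scale, against 0.21 with upper-quartile scaling. TMM factors were 1.13 to 1.19 in untreated and 0.764 to 0.946 in IR-treated libraries. FPKM values scaled to total counts would lack them and so fall with IR. FPKM splits with IR can therefore carry a scaling offset and do not by themselves set direction.

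In sgRnf19a cells IR raised interferon and chemokine genes. Ifnb1 went from 0.252 ± 0.133 CPM to 24.9 ± 3.15 CPM, 98.4-fold higher (log2 fold change 6.62, SE 0.35, edgeR adjusted p = 6.05e-07, n = 3 per group), and Cxcl10 rose 75.3-fold (log2 fold change 6.23, SE 0.26). Cxcl9 had 955 counts in sgRnf19a_IR against 7 in sgRnf19a. Of 65 interferon-stimulated genes 54 rose and 0 fell (56 and 0 adjusted over the list alone; camera adjusted p = 3.00e-25, adjusted p = 0.170 with an estimated correlation). Ifit1 was 50.3-fold, Cmpk2 19.1-fold, Usp18 16.5-fold and Zbp1 12.5-fold higher. Cd274, which encodes the checkpoint ligand PD-L1, went from 9.08 ± 1.67 CPM to 116 ± 52.4 CPM (log2 fold change 3.67, SE 0.32, edgeR adjusted p = 2.15e-05). Cgas rose 2.04-fold (log2 fold change 1.03, SE 0.27, edgeR adjusted p = 0.0122), a call lost without sgRnf19a replicate 2 (edgeR adjusted p = 0.0580) and with log2(FPKM + 0.1).

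Of 24 MHC class I and antigen processing genes 17 rose and 2 fell (17 and 2 adjusted over the list alone), with Tapbpl 5.67-fold and Psmb10 4.44-fold higher (camera adjusted p = 1.47e-06, adjusted p = 0.263 with an estimated correlation). NF-kB targets, cytokines and chemokines included 40 tested genes; 18 rose and 3 fell (19 and 3 adjusted over the list alone), Il15 by 28.6-fold and Ccl2 by 9.49-fold (camera adjusted p = 7.43e-06, adjusted p = 0.373 with an estimated correlation). Cytosolic nucleic acid sensing and type I interferon genes gave 30 tested members; 13 rose and 6 fell (14 and 6 adjusted over the list alone), Socs1 8.82-fold and Samhd1 2.41-fold higher (camera adjusted p = 0.0482, adjusted p = 0.373 with an estimated correlation). On the FPKM scale, however, 9 rose and 10 fell of 29, with a median of -0.13. Among 27 cholesterol synthesis genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), Fdft1 2.85-fold and Cyp51 2.33-fold higher (camera adjusted p = 0.000615, adjusted p = 0.486 with an estimated correlation). Of 40 mitosis genes 4 rose and 19 fell (5 and 24 adjusted over the list alone), Cenpf falling 12.3-fold and Mki67 10.5-fold (camera adjusted p = 0.00150, adjusted p = 0.454 with an estimated correlation). Of 36 DNA repair genes 0 rose and 24 fell (1 and 24 adjusted over the list alone), with Brca2 8.71-fold and Trp53bp1 2.80-fold lower (camera adjusted p = 2.21e-06, adjusted p = 0.578 with an estimated correlation). The MAPK pathway and immediate early list moved by 0.16 in median: 11 rose and 5 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.244). Atf3 was 17.4-fold and Jun 3.91-fold higher, and on the FPKM scale 7 and 13 rose and fell, with a list median of -0.29. For p53 target genes 13 rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.227). Bax was 2.79-fold and Cdkn1a 1.79-fold higher, and on the FPKM scale 2 rose and 14 fell. The Cdkn1a call was lost with only the 2 groups compared and on the FPKM scale. After the length and GC correction the genes called higher and lower, with those kept and the list median, were 57 and 0 (52 and 0 kept, 1.83) for interferon-stimulated, 16 and 2 (16 and 2 kept, 0.60) for MHC class I, 18 and 4 (16 and 2 kept, 0.44) for NF-kB, 15 and 5 (13 and 4 kept, 0.32) for nucleic acid sensing, 19 and 0 (12 and 0 kept, 0.53) for cholesterol, 5 and 31 (4 and 18 kept, -0.82) for mitosis, 0 and 22 (0 and 21 kept, -0.48) for DNA repair, 12 and 7 (9 and 4 kept, 0.16) for MAPK and 16 and 5 (11 and 1 kept, 0.28) for p53 target genes.

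The rRNA share and short transcripts again moved with IR. Of 59 histone genes 49 rose and 0 fell (54 and 0 adjusted over the list alone; camera adjusted p = 7.34e-20, adjusted p = 0.243 with an estimated correlation). Of 85 ribosomal protein genes 82 rose and 0 fell (84 and 0 adjusted over the list alone; camera adjusted p = 6.74e-31, adjusted p = 0.462 with an estimated correlation). Among 34 respiratory chain genes 29 rose and 0 fell (30 and 0 adjusted over the list alone; camera adjusted p = 3.66e-11, adjusted p = 0.486 with an estimated correlation). Among 31 proteasome genes 21 rose and 1 fell (24 and 1 adjusted over the list alone; camera adjusted p = 3.12e-07, adjusted p = 0.462 with an estimated correlation). After the correction the genes called higher and lower, with those kept and the median, were 38 and 0 (38 and 0 kept, 1.89) for histone, 57 and 3 (57 and 0 kept, 0.61) for ribosomal protein, 15 and 6 (15 and 0 kept, 0.21) for respiratory chain and 15 and 3 (15 and 1 kept, 0.25) for proteasome genes. The largest rises also held Rpph1, the RNA of RNase P (79.4-fold), Ifit1bl1 (146-fold) and Ifna4 (668 counts against 11); Ifit1bl1 and Ifna4 have close relatives and are uncertain. The largest falls were Zfp820 (13.3-fold), Cenpf, Mki67, Zfp808 (9.86-fold), Clca1 (9.22-fold) and Cep290 (9.03-fold). The Clca1 call was lost without sgRnf19a replicate 1, 2 or 3 or sgRnf19a_IR replicate 1 or 3 (edgeR adjusted p from 0.0641 to 0.119). It was also lost with DESeq2, no filter or only the 2 groups compared. Where the correction moved a fold change given above for this comparison by over 1.5 times with the call kept, the corrected fold changes were Ifnb1 44.9, Cxcl10 48.4, Psmb10 2.77, Ccl2 4.70, Cenpf 5.46, Mki67 5.37, Brca2 3.80, Trp53bp1 1.36, Bax 1.49, Rpph1 30.9, Zfp820 8.27 and Cep290 4.06.

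IR in sgRnf19a cells raised 3266 and lowered 3209 genes by edgeR at an adjusted p under 0.05. The libraries did not overlap for 49.8% of genes, where chance gives 10%. Without sgRnf19a_IR replicate 4 the total of 6475 became 8773, beside 8707 for IR in control cells. With only the 2 groups compared the totals were 4418 and 9125. The lower total depends on that library and does not by itself show a weaker response. On the FPKM scale the split was 1810.0 higher and 6304 lower, with the median of all genes shifted by -0.44; upper-quartile scaling shifted it by 0.11. After the length and GC correction 6787 were called, 4283 of them among the 6475 and 4109 in the same direction. The IR responses of the 2 genotypes, which share no library, had 2620.0 genes raised in both and 2480.0 lowered in both, and 2394 and 2582 after the length and GC correction. Both responses carry the shift in rRNA share and transcript length, so a number of shared genes can come from it as well as from the cells.

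Without IR, sgRnf19a cells held more mRNA of interferon-stimulated and antigen presentation genes than control cells. Of 65 interferon-stimulated genes 58 rose and 0 fell (61 and 0 adjusted over the list alone), with a median log2 fold change of 2.14 (camera adjusted p = 1.73e-63, adjusted p = 0.0508 with an estimated correlation). Rtp4 was 20.8-fold higher (log2 fold change 4.38, SE 0.15, edgeR adjusted p = 3.98e-08, n = 3 per group), Zbp1 7.59-fold, Irf7 6.71-fold and Isg15 6.34-fold. Oas1a and Oas1g were each higher (13.7-fold and 13.7-fold) but are near-identical and uncertain. Cgas (ENSMUSG00000032344, mm10 chromosome 9, 78430526 to 78443237) went from 1.73 ± 0.126 CPM to 14.7 ± 2.03 CPM, 8.53-fold higher (log2 fold change 3.09, SE 0.30, edgeR adjusted p = 5.35e-05). Ifnb1 was at 0.194 ± 0.0472 CPM in control and 0.252 ± 0.133 CPM in sgRnf19a cells, a difference that did not pass (log2 fold change 0.37, SE 0.36, edgeR adjusted p = 0.694).

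Of 24 MHC class I and antigen processing genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.65e-12, adjusted p = 0.150 with an estimated correlation). Tap1 went from 18.1 ± 2.95 CPM to 90.4 ± 0.714 CPM (log2 fold change 2.32, SE 0.21, edgeR adjusted p = 3.83e-05) and the immunoproteasome gene Psmb8 rose 5.71-fold. H2-K1, from 149 ± 23.3 CPM to 746 ± 21.8 CPM, H2-T23 (5.22-fold) and H2-Q4 (8.29-fold) belong to a family with shared reads and are uncertain. Cd274 (ENSMUSG00000016496, mm10 chromosome 19, 29367455 to 29388095) rose from 3.05 ± 0.761 CPM to 9.08 ± 1.67 CPM (log2 fold change 1.57, SE 0.30, edgeR adjusted p = 0.00756), a call lost with log2(FPKM + 1) with or without a filter, and Lgals9 rose 4.25-fold. Among 39 p53 target genes 7 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.000803, adjusted p = 0.229 with an estimated correlation). Ddb2, a nucleotide excision repair gene, was 2.94-fold and Pmaip1, which encodes the BH3 protein NOXA, 2.09-fold higher (lost on FPKM with no filter), and Ak1 3.93-fold lower. Extracellular matrix genes went the other way: of 39, 2 rose and 8 fell (2 and 10 adjusted over the list alone; camera adjusted p = 5.36e-06, adjusted p = 0.243 with an estimated correlation). Col6a1 fell 4.91-fold, Serpine2 4.41-fold and Tnc 3.54-fold. Of 12 fibroblast markers 0 rose and 3 fell (1 and 3 adjusted over the list alone), with Pdgfrb 3.83-fold lower. Fap, not called over all genes, went the other way, with 256 counts in sgRnf19a and 5 in control. That list had camera adjusted p = 0.00783, adjusted p = 0.593 with an estimated correlation and 0.160 with a replicate block. Of 37 mitochondrially encoded genes 1 rose and 11 fell (1 and 14 adjusted over the list alone; camera adjusted p = 0.00481, adjusted p = 0.679 with an estimated correlation). Of 32 hypoxia and glycolysis genes 0 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.00899, adjusted p = 0.679 with an estimated correlation). Ribosomal protein genes had a median of -0.46, and 0 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 5.47e-10, adjusted p = 0.679 with an estimated correlation). Respiratory chain genes had a median of -0.43, and 0 rose and 3 fell (0 and 8 adjusted over the list alone; camera adjusted p = 5.57e-07, adjusted p = 0.633 with an estimated correlation). Both groups are short transcripts, beside the difference in long-minus-short level given above. After the length and GC correction the genes called higher and lower, with those kept and the list median, were 60 and 0 (58 and 0 kept, 2.04) for interferon-stimulated, 16 and 1 (14 and 1 kept, 1.06) for MHC class I, 11 and 1 (6 and 1 kept, 0.35) for p53 target, 2 and 12 (2 and 8 kept, -0.36) for matrix, 0 and 3 (0 and 3 kept, -0.36) for fibroblast, 1 and 5 (1 and 4 kept, -0.15) for mitochondrially encoded, 1 and 5 (0 and 5 kept, -0.14) for hypoxia, 0 and 2 (0 and 0 kept, -0.17) for ribosomal protein and 0 and 3 (0 and 1 kept, -0.24) for respiratory chain genes.

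Some single genes differed by far more. Grb10, an imprinted gene for an adaptor of growth factor receptors, was at 319.6 ± 15.2 CPM in control and 1.63 ± 1.71 CPM in sgRnf19a cells (log2 fold change -7.61, SE 0.64, edgeR adjusted p = 1.84e-05). Dsp, the desmosome gene, went the other way (log2 fold change 6.76, SE 0.35, edgeR adjusted p = 7.30e-07), as did Mbnl3 (81.2-fold), Cntln (49.2-fold), Itih5 (43.8-fold) and Magohb (39.3-fold). Esx1 (177-fold), Tbx18 (151-fold) and Tmem47 (67.8-fold) were lower. Hhat had 1070.0 counts in sgRnf19a and 4 in control, Gpr149 had 4 and 2041, and Cd163 had 12 and 2257. In all, edgeR called 549 genes higher and 582 lower, and the libraries did not overlap for 38.2% of genes, where chance gives 10%. The total of 1131 fell to 685 without control replicate 1, 707 without control replicate 3, 642 without sgRnf19a replicate 2 and 648 without sgRnf19a replicate 3. It rose to 1778 with DESeq2, 1833 after the length and GC correction, 2825 with only the 2 groups compared and 3262 with a replicate block.

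**Figure D3:**
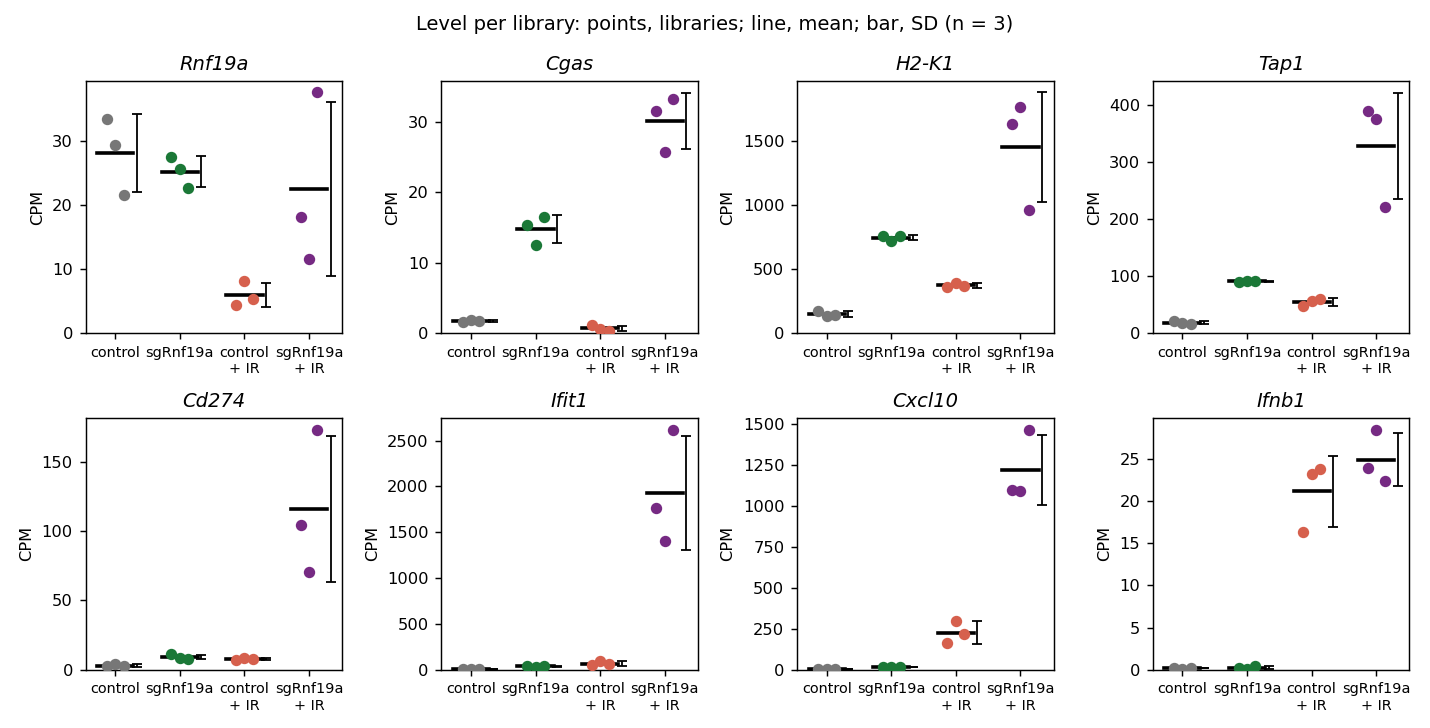
CPM per library of Rnf19a, Cgas, H2-K1, Tap1, Cd274, Ifit1, Cxcl10 and Ifnb1 in the 4 groups (points, libraries; line, mean; bar, SD, n = 3), each axis starting at 0. Cgas stands at 1.73 ± 0.126 CPM in control, 14.7 ± 2.03 CPM in sgRnf19a, 0.665 ± 0.397 CPM in control_IR and 30.1 ± 3.95 CPM in sgRnf19a_IR libraries.

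Among IR-treated cells the guide went with higher interferon-stimulated and antigen presentation genes. Of 65 interferon-stimulated genes 63 rose and 0 fell (63 and 0 adjusted over the list alone), with a median log2 fold change of 3.30 (camera adjusted p = 1.60e-40, adjusted p = 0.108 with an estimated correlation). Zbp1 was 18.6-fold and Rtp4 11.7-fold higher. Ifit1 went from 67.7 ± 24.5 CPM to 1928 ± 626 CPM (log2 fold change 4.83, SE 0.32, edgeR adjusted p = 2.31e-06, n = 3 per group). Cgas went from 0.665 ± 0.397 CPM to 30.1 ± 3.95 CPM, 46.2-fold higher (log2 fold change 5.53, SE 0.35, edgeR adjusted p = 1.69e-06). After the length and GC correction it stayed higher (log2 fold change 4.92, edgeR adjusted p = 7.91e-07). Cd274 rose from 7.67 ± 0.769 CPM to 116 ± 52.4 CPM (log2 fold change 3.91, SE 0.32, edgeR adjusted p = 1.14e-05). Ifnb1, at 21.1 ± 4.19 CPM and 24.9 ± 3.15 CPM, did not differ detectably (log2 fold change 0.24, SE 0.26, edgeR adjusted p = 0.534).

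Of 24 MHC class I and antigen processing genes 19 rose and 0 fell (20 and 1 adjusted over the list alone; camera adjusted p = 5.25e-11, adjusted p = 0.160 with an estimated correlation), with Nlrc5, the MHC class I transactivator, 8.84-fold, Tap1 6.08-fold and Psmb8 5.88-fold higher. Immediate early genes went the other way: of 33 in the MAPK list 4 rose and 18 fell (4 and 18 adjusted over the list alone; camera adjusted p = 0.000557, adjusted p = 0.633 with an estimated correlation). Jun fell from 287 ± 25.2 CPM to 77.6 ± 17.6 CPM (log2 fold change -1.89, SE 0.17, edgeR adjusted p = 2.49e-05), Egr3 3.96-fold and Dusp1 2.13-fold lower. Among 36 DNA repair genes, many of them long, 23 rose and 3 fell (27 and 5 adjusted over the list alone; camera adjusted p = 0.00462, adjusted p = 0.679 with an estimated correlation). Fancd2 was 3.18-fold higher and H2ax 2.66-fold lower; after a correction for length and GC content 9 of those rises and 2 of those falls were still called. Of 27 cholesterol synthesis genes 3 rose and 11 fell (3 and 11 adjusted over the list alone), Dhcr7 being 2.29-fold lower (camera adjusted p = 0.0389, adjusted p = 0.679 with an estimated correlation). Of 34 respiratory chain genes 2 rose and 7 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.000124, adjusted p = 0.679 with an estimated correlation). Of 85 ribosomal protein genes 6 rose and 3 fell (1 and 0 adjusted over the list alone) around a median of -0.37 (camera adjusted p = 0.000733, adjusted p = 0.838 with an estimated correlation). The split was not stable: 4 rose and 8 fell with upper-quartile scaling, 5 and 7 on the FPKM scale and 13 and 16 after the length and GC correction. Of 37 mitochondrially encoded genes 3 rose and 13 fell (3 and 15 adjusted over the list alone) around a median of -0.35 (camera adjusted p = 0.00959, adjusted p = 0.680 with an estimated correlation), and 0 rose and 22 fell around -1.04 after the length and GC correction. For histone genes 0 rose and 2 fell (0 and 0 adjusted over the list alone) around a median of -0.36 (camera adjusted p = 0.00783, adjusted p = 0.679 with an estimated correlation), a median that turned to 0.16 after that correction. With it the genes called higher and lower, with those kept and the list median, were 63 and 0 (63 and 0 kept, 3.08) for interferon-stimulated, 20 and 1 (19 and 0 kept, 1.83) for MHC class I, 5 and 13 (2 and 12 kept, -0.32) for MAPK, 10 and 5 (9 and 2 kept, 0.23) for DNA repair, 3 and 13 (0 and 7 kept, -0.33) for cholesterol and 5 and 15 (1 and 5 kept, -0.31) for respiratory chain genes.

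Grb10, Esx1, Tbx18, Gpr149 and Cd163, lower with the guide without IR, were lower with it here too. Grb10 was at 152 ± 21.2 CPM in control_IR and 3.05 ± 0.157 CPM in sgRnf19a_IR (log2 fold change -5.64, SE 0.59, edgeR adjusted p = 6.19e-05), with Esx1 106-fold and Tbx18 58.1-fold lower. Gpr149 had 6 counts in sgRnf19a_IR against 723, Cd163 9 against 587 and Gng11 10 against 452. Cdh15 was 87.9-fold higher, Dynap had 511 counts against 8, and Tgtp1 (64.8-fold) and Ifit1bl1 (56.2-fold), higher too, have close relatives and are uncertain. Myh11, with 0 counts in control_IR and thus at least 47.0-fold higher against the floor of 12 counts, and Eln (log2 fold change 7.54, SE 2.36) varied within groups. The Myh11 call was lost without any 1 of the 6 IR-treated libraries (edgeR adjusted p from 0.0658 to 0.139). So was the Eln call (edgeR adjusted p from 0.0510 to 0.116). Both calls were also lost with no filter, on FPKM with no filter and after the length and GC correction, and that of Myh11 with counts divided by 4. Where that correction moved another fold change given above for this comparison by over 1.5 times with the call kept, the corrected fold changes were Ifit1 16.4, Cgas 30.2, Cd274 8.95, Fancd2 1.84, H2ax 1.38, Tbx18 87.2, Tgtp1 37.9 and Ifit1bl1 31.7. Of the genes the guide raised without IR, 447 of 549 were also raised with IR, and of those it lowered 452 of 582. After the length and GC correction 622 of 862 and 726 of 971 were shared, where independent lists would share 122 and 147. These comparisons share no library. A difference between the sgRnf19a and control cultures that the guide did not make would still recur in both. The numbers expected of independent lists therefore do not separate the guide from the cultures.

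EdgeR called 3812 genes higher and 2328 lower with the guide in IR-treated cells, and the libraries did not overlap for 42.5% of genes, where chance gives 10%. The split was 2537 and 2454 on the FPKM scale and 2577 and 2758 after the length and GC correction (3542 shared, 3493 in the same direction), and upper-quartile scaling shifted the median of all genes by -0.13. The total of 6140.0 fell to 3877 without control_IR replicate 1 and was 4880.0 without sgRnf19a_IR replicate 4, the library that lay apart. Without a change between these 2 groups the simulated trends gave 474 genes here, and 0 after correction, the latter built in as above.

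**Figure D4:**
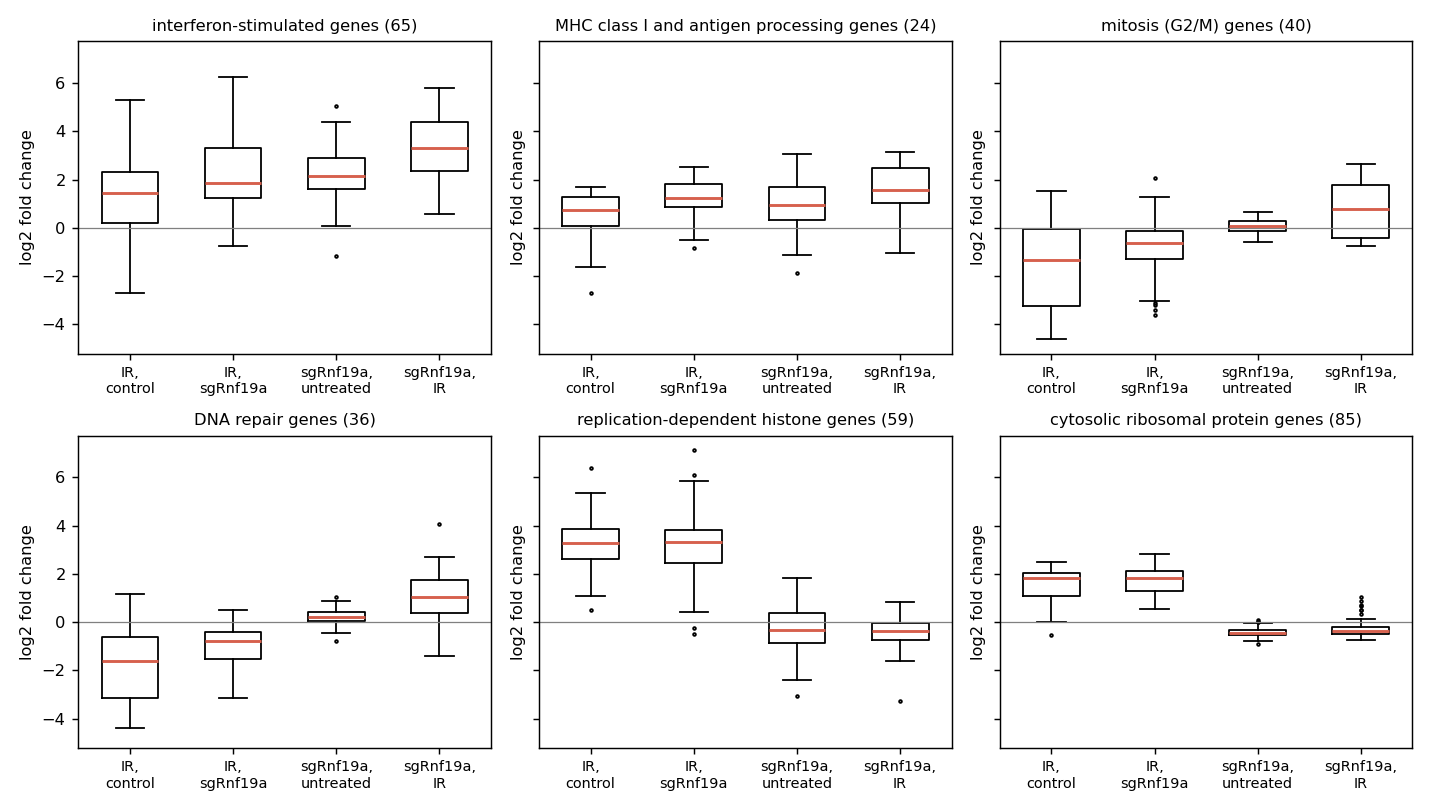
Log2 fold changes of the tested members of 6 gene lists in the 4 comparisons between 2 groups (red line, median; box, quartiles; whiskers, 1.5 box lengths; points, genes beyond). The interferon-stimulated genes have medians of 1.45, 1.85, 2.14 and 3.30, while the histone gene median of the guide in IR-treated cells, -0.36, turns to 0.16 after a length and GC correction.

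The last comparison asked where the IR response itself differed between genotypes. Some interferon-stimulated genes rose more with IR in sgRnf19a than in control cells: Ifit1 by a further 4.96-fold (log2 fold change 2.31, SE 0.39, edgeR adjusted p = 0.0283, n = 3 per group), Ifit3 by 7.39-fold, Gbp2 by 7.59-fold, Zbp1 by 2.45-fold and Trim21 by 3.06-fold. Of 65 in the list, 11 passed with a positive difference and 0 with a negative one (37 and 3 adjusted over the list alone; camera adjusted p = 9.06e-09, adjusted p = 0.462 with an estimated correlation). Cd274 (log2 fold change 2.34, SE 0.42, edgeR adjusted p = 0.0318) also rose more in sgRnf19a cells. Cgas (log2 fold change 2.44, SE 0.42, edgeR adjusted p = 0.0318) fell with IR in control and rose in sgRnf19a cells, at log2 fold changes of -1.41 and 1.03. The 2 values were -0.57 and 1.38 after the length and GC correction, where the fall was not called. The rise was lost without sgRnf19a replicate 2 (edgeR adjusted p = 0.0580). Isg15 (log2 fold change -0.40, SE 0.27, edgeR adjusted p = 0.427), Irf7 (log2 fold change -0.29, SE 0.24), H2-K1 (log2 fold change -0.36, SE 0.28), Cxcl10 (log2 fold change 0.92, SE 0.29) and Ifnb1 (log2 fold change -0.13, SE 0.44) did not pass.

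MHC class I and antigen processing genes gave 2 positive and 0 negative differences of 24 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00112, adjusted p = 0.462 with an estimated correlation), Nlrc5 differing by 3.36-fold. The cytokine genes Il15 (7.91-fold), Il6 (7.24-fold), Ccl2 (2.64-fold) and the receptor gene Ccrl2 (5.12-fold) rose more in sgRnf19a cells. The length and GC correction ended the calls of Il6 (log2 fold change 2.13, edgeR adjusted p = 0.0589) and Ccl2 (0.73, edgeR adjusted p = 0.162). Of 33 MAPK pathway and immediate early genes, 2 passed with a negative difference and 0 with a positive one (8 and 2 adjusted over the list alone; camera adjusted p = 0.000290, adjusted p = 0.633 with an estimated correlation). These were Jun at -1.47 and Fosb at -1.63 on the log2 scale. The largest positive differences were those of Angpt1 (18.0-fold), Tmem47 (13.1-fold), Sp110 (11.2-fold), Ifit1bl1 (10.9-fold, uncertain), Etl4 (9.41-fold) and Casp12 (9.23-fold). With IR in control and in sgRnf19a cells, Tmem47 was at log2 fold changes of -2.93 and 0.78, Sp110 at -1.56 and 1.93, Etl4 at -1.53 and 1.71 and Casp12 at -2.01 and 1.20. In control cells the corrected values were -1.06, -1.92, -0.26 and -0.52. Only that of Sp110 passed. The most negative differences were Relt (-2.24), Aqp3 (-2.13), Dsp (-2.10), Lockd (-1.76), Fosb and Cdx2 (-1.60). The Tmem47 call too was lost after that correction (edgeR adjusted p = 0.0652). Other named log2 values whose fold it moved by over 1.5 times with the call kept became Ifit1 1.68, Cd274 1.72, Angpt1 2.95, Ifit1bl1 2.78, Casp12 2.27 and Lockd -2.41, and the positive and negative differences, with those kept and the list median, became 22 and 3 (11 and 0 kept, 0.94) for interferon-stimulated, 7 and 0 (2 and 0 kept, 0.67) for MHC class I and 1 and 5 (0 and 2 kept, -0.25) for MAPK genes. Of 99 genes that edgeR called with a positive difference, 31 had risen with IR in both genotypes, 34 in sgRnf19a cells alone and 18 had fallen in control and risen in sgRnf19a cells. With IR responses taken after the length and GC correction the 3 counts were 53, 27 and 13. A negative difference was called for 25, and 3858 had an unadjusted p under 0.05. The split into positive and negative was 330 and 181 after the length and GC correction, 1300 and 395 with DESeq2 and 48 and 7 with log2(FPKM + 0.1). Each of the 12 libraries moved the total of 124 by over 1.5 times when left out. It was 38, 33 and 26 without control replicates 1, 2 and 3, and 72, 10 and 11 without sgRnf19a replicates 1, 2 and 3. With IR-treated libraries left out it was 23, 81 and 5 without control_IR replicates 1, 4 and 5, and 34, 2624 and 500 without sgRnf19a_IR replicates 1, 3 and 4. With at least 1 of the FPKM settings the calls of Angpt1, Casp12, Ccl2, Ccrl2, Cd274, Cdx2, Cgas, Dsp, Fosb, Lockd, Nlrc5, Relt and Sp110 were lost, with no filter those of Cdx2 and Lockd, with upper-quartile factors that of Il6 and with counts divided by 4 those of Dsp and Ifit1bl1. Of 25 called genes named here, 24 lost the call without at least 1 library (edgeR adjusted p from 0.0508 to 0.150). These were 13, 24 and 22 without sgRnf19a replicates 1, 2 and 3, and 20 without sgRnf19a_IR replicate 1. They were 17, 17 and 20 without control replicates 1, 2 and 3, and 21, 12 and 24 without control_IR replicates 1, 4 and 5.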

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

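The tests of RNA kinds, of length and GC content, of leukocyte genes, of differences between cultures, of depth and of intestinal genes were chosen only after the result was seen, and the levels of some intestinal genes had been looked at before that list was drawn up; only the splits of the libraries were set beforehand.

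The IR response differed between genotypes for 124 genes by the edgeR test of the difference itself, which is what marked these results. By log2 difference these included Angpt1 4.17, Tmem47 3.72, Sp110 3.48, Ifit1bl1 3.45, Etl4 3.23, Casp12 3.21, Il15 2.98, Gbp2 2.92, Ifit3 2.89, Il6 2.86, Cgas 2.44, Ccrl2 2.36, Cd274 2.34, Ifit1 2.31, Nlrc5 1.75, Trim21 1.62, Ccl2 1.40 and Zbp1 1.29. Negative differences were those of Jun -1.47, Cdx2 -1.60, Fosb -1.63, Lockd -1.76, Dsp -2.10, Aqp3 -2.13 and Relt -2.24. Of 100 drawn splits of the genotype among the 200 possible, 6 gave as many genes, the real one included, and the highest other gave 2171. A split with several times the real count points to a structure of the samples, which here is the guide itself. Those 5 exchange the genotype of 4 untreated libraries alone, or of 2 untreated and all 6 IR-treated ones, which carries the effect of the guide into the difference. The 38 drawn splits that exchange equal numbers in both treatments gave at most 0 genes, but they mix the genotypes within each group. The splits therefore say nothing on chance for this difference. For the other 4 comparisons 10 splits are too few for a share under 0.05. In each, 1 split reached the real count: 8707 against a highest other of 1 for IR in control cells, 6475 against 1 for IR in sgRnf19a cells, 1131 against 9 for the guide in untreated cells and 6140.0 against 0 in IR-treated cells.

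The IR-treated libraries held more short and less long RNA, and log2 fold changes with IR also went with GC content (rho 0.533 and 0.275). Transcript length alone is argued against: histone genes under 1 kb exceeded ribosomal protein genes under 1 kb by 1.35 in median log2 fold change, a little more than their summed median absolute deviations of 1.30. Untailed RNA kept in these libraries is a candidate explanation, since small structural RNAs and histone genes exceeded ribosomal protein genes by 1.52. The labels, however, give rRNA depletion for all 12 libraries, which would keep untailed RNA in the untreated ones too, and there the 7SL RNA gene Rn7s1 was at 0.330 CPM against 18.4 CPM in control_IR. A response of the cells to IR stays open, as the lowest gap in rRNA share between the treatments, 10.6 percentage points, falls on the same libraries as IR and cannot be told apart from it.

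Interferon-stimulated genes were higher in sgRnf19a cells. Length and GC content are argued against as the whole cause, as 58 genes called higher without IR and 63 with IR were still called after that correction. A larger share of immune cells in the untreated sgRnf19a cultures is argued against by Ptprc, Lyz2, Csf1r and Cd68. Their mean log2 fold change was 0.20 (SE 0.32, which treats the 4 genes as independent) against a list median of 2.14. In untreated control cells these genes were at 4.24, 7.45, 9.86 and 27.3 CPM, so the values do not speak to immune cells present in both genotypes. Lyz2 by itself, however, was at 1.80 (SE 0.92, edgeR adjusted p = 0.364), beside Ptprc at -0.64 (SE 0.60, edgeR adjusted p = 0.672), Csf1r at -0.29 (SE 0.61, edgeR adjusted p = 0.868) and Cd68 at -0.06 (SE 0.23, edgeR adjusted p = 0.940). Differences between the 2 cultures that the guide did not make cannot be told apart from the guide, because the labels name 1 guide per genotype, and 107 called genes differed by an absolute log2 fold change of 4 or more. An effect of Rnf19a loss may explain the pattern and stays open as a hypothesis.

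Melanocyte genes were near 0 in cells named as B16F10. Tyr, Tyrp1, Mlana and Slc45a2 had 0 counts in all 12 libraries, and 7 of 8 such genes, the lineage factor gene Sox10 included and Mitf not, were under 1 CPM in every library. Depth is argued against, as 3 read pairs over the untreated libraries correspond to 0.0263 CPM. Cells of another line cannot be told apart from B16F10 cells that have lost melanocyte genes: of 12 intestinal epithelial genes, taken as 1 other lineage, 4 reached 1 CPM in control cells, the most abundant being Krt19 at 145 ± 36.3 CPM. Krt8 and Krt18, keratin genes of simple epithelia, were at 351 and 254 CPM there, and no other lineage was tested.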

How the results depend on the processing

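The length and GC correction, the division of counts by 4 and the block on column numbers were chosen only after the data were seen; the other alternatives were planned. Of 2956 values of named genes under an alternative, 2685 kept direction and side of the threshold, 261 lost the call, 1 gained one, 0 reversed and 9 changed sign without a call; the cause was not tested. Of the named called genes, 0 of 38, 2 of 33, 0 of 32, 2 of 27, 24 of 25 lost the call without at least 1 library in the 5 comparisons in the order of the report. Many of these genes were named for a large fold change without overlap between libraries, or for a small p, in these same data. That favours keeping the call, and the rule on overlap was not used for the difference between IR responses. The shares therefore do not describe all called genes, whose totals are given below. In leave-one-out fits an arm of 2 libraries shares the spread of the other groups.

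Requiring an absolute log2 fold change of 1 left 5609, 3582, 745 and 3473 genes in the 4 comparisons of 2 groups, by construction. DESeq2 called 1778 for the guide in untreated cells and 1695 for the difference between IR responses. With only the 2 groups compared the guide gave 2825 genes without IR and 2797 with IR. The FPKM values gave 2952 for the guide with IR without a filter, and 55 for the difference with a pseudocount of 0.1. The length and GC correction gave 1833 for the guide without IR (1065 shared) and 511 for the difference (101 shared). Leaving out 1 library gave 7383 to 8144, 4722 to 8773, 642 to 911, 3877 to 7612 and 5 to 2624 genes in the 5 comparisons. All 5 sets of list calls came to 0 with an estimated correlation. Where no construction shows it, the cause was not tested.

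For Rnf19a, IR in sgRnf19a cells gave 0.16 after the length and GC correction and passed at -0.77 without sgRnf19a_IR replicate 4, and the difference between IR responses passed at 2.06 with DESeq2, 1.40 after the correction, 2.39 without sgRnf19a_IR replicate 3 and 1.48 without sgRnf19a_IR replicate 4. Leaving out 1 library gave log2 fold changes of -2.54 to -2.07, -0.77 to 0.13, -0.32 to -0.01, 1.32 to 2.23 and 1.48 to 2.39.

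With the replicate number as a replicate block, the 6 untreated libraries gave 3262 genes, and 10 lists by camera and 8 by fry. Same-numbered libraries correlated at -0.157 to 0.0329 in their deviations, 0 of 6 correlating best with its own number, so they share only a number. The IR-treated columns carry numbers that are not those of the labels. Of these, 1 and 4 occur in both genotypes, and a block on them gave 5107 genes for the guide (4316 shared); those 2 pairs correlated at -0.00290 and 0.0790. The other 3 comparisons were not blocked, since the numbers of the IR-treated columns are not those of the labels. Depth limits genes near 12 counts over a group.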

Other observations

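The gene lists were set before the data were examined, and of the scalings in the last paragraph the length and GC correction was chosen only after the result was seen. Counts marked corrected follow that correction and stand where it moved a count by over 1.5 times and at least 3 genes.

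Of 27 tested checkpoint and immune receptor ligand genes, IR left 5 higher and 5 lower (5 and 5 adjusted over the list alone) in control cells. Checkpoint genes were 8 higher and 3 lower (8 and 3 adjusted over the list alone) with IR in sgRnf19a cells. Checkpoint genes were 4 higher and 2 lower (5 and 3 adjusted over the list alone) with the guide in untreated cells. Checkpoint genes were 11 higher and 1 lower (12 and 2 adjusted over the list alone, 7 and 4 corrected) with the guide in IR-treated cells. Checkpoint genes had 1 higher and 0 lower (1 and 0 adjusted over the list alone) for the difference between IR responses. Of 30 tested nucleic acid sensing genes, IR left 12 higher and 10 lower (12 and 10 adjusted over the list alone) in control cells. Nucleic acid sensing genes were 3 higher and 0 lower (5 and 1 adjusted over the list alone) with the guide in untreated cells. Nucleic acid sensing genes were 12 higher and 3 lower (12 and 3 adjusted over the list alone) with the guide in IR-treated cells. Nucleic acid sensing genes had 2 higher and 0 lower (7 and 1 adjusted over the list alone; 5 and 0 corrected) in their response to IR in sgRnf19a against control cells. Of 38 tested DNA replication genes, IR left 16 higher and 12 lower (16 and 14 adjusted over the list alone) in control cells. DNA replication genes were 16 higher and 8 lower (17 and 9 adjusted over the list alone) with IR in sgRnf19a cells. DNA replication genes were 0 higher and 0 lower (0 and 0 adjusted over the list alone) with the guide in untreated cells. DNA replication genes were 8 higher and 8 lower (11 and 11 adjusted over the list alone; 3 and 10 corrected) with the guide in IR-treated cells. DNA replication genes had 1 higher and 0 lower (1 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells. Pcna, the sliding clamp gene, was 2.98-fold higher with IR in control cells. Of 44 tested RBR ligase, RSK and ubiquitin genes, IR left 11 higher and 15 lower (11 and 15 adjusted over the list alone) in control cells. Ubiquitin genes were 7 higher and 10 lower (9 and 11 adjusted over the list alone, 14 and 9 corrected) with IR in sgRnf19a cells. Ubiquitin genes were 2 higher and 0 lower (2 and 0 adjusted over the list alone) with the guide in untreated cells. Ubiquitin genes were 13 higher and 5 lower (14 and 6 adjusted over the list alone, 13 and 9 corrected) with the guide in IR-treated cells. Ubiquitin genes had 0 higher and 0 lower (7 and 0 adjusted over the list alone, 3 and 1 corrected) for the difference between IR responses. Rnf19b, the closest relative of Rnf19a, rose 3.52-fold with IR in sgRnf19a cells. In control cells its mean was higher with IR too, at 33.7 ± 4.66 CPM untreated and 57.9 ± 1.83 CPM with IR. Of 35 tested stress response genes, IR left 12 higher and 12 lower (12 and 12 adjusted over the list alone) in control cells. Stress response genes were 12 higher and 8 lower (12 and 8 adjusted over the list alone) with IR in sgRnf19a cells. Stress response genes were 1 higher and 3 lower (2 and 4 adjusted over the list alone; 4 and 4 corrected) with the guide in untreated cells. Stress response genes were 11 higher and 4 lower (13 and 4 adjusted over the list alone) with the guide in IR-treated cells. Stress response genes had 1 higher and 0 lower (3 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells.

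Of 32 tested hypoxia and glycolysis genes, IR left 5 higher and 9 lower (5 and 9 adjusted over the list alone) in control cells. Hypoxia genes were 6 higher and 4 lower (6 and 4 adjusted over the list alone, 6 and 8 corrected) with IR in sgRnf19a cells. Hypoxia genes were 6 higher and 5 lower (6 and 5 adjusted over the list alone) with the guide in IR-treated cells. Hypoxia genes had 0 higher and 0 lower (5 and 0 adjusted over the list alone) for the difference between IR responses. Of 35 tested lysosome and autophagy genes, IR left 10 higher and 5 lower (10 and 5 adjusted over the list alone; 9 and 12 corrected) in control cells. Lysosome genes were 10 higher and 3 lower (10 and 3 adjusted over the list alone, 10 and 10 corrected) with IR in sgRnf19a cells. Lysosome genes were 1 higher and 0 lower (0 and 0 adjusted over the list alone) with the guide in untreated cells. Lysosome genes were 7 higher and 1 lower (5 and 1 adjusted over the list alone, 11 and 3 corrected) with the guide in IR-treated cells. Lysosome genes had 0 higher and 0 lower (2 and 1 adjusted over the list alone) for the difference between IR responses. Of 18 tested melanocyte pigmentation genes, IR left 1 higher and 5 lower (1 and 5 adjusted over the list alone) in control cells. Pigmentation genes were 2 higher and 3 lower (0 and 3 adjusted over the list alone) with IR in sgRnf19a cells. Pigmentation genes were 1 higher and 1 lower (2 and 1 adjusted over the list alone) with the guide in untreated cells. Pigmentation genes were 5 higher and 1 lower (5 and 1 adjusted over the list alone) with the guide in IR-treated cells. Pigmentation genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone) for the difference between IR responses. Mitf, the melanocyte transcription factor gene, fell 4.50-fold with IR in control cells (1.67-fold after the length and GC correction). Of 37 tested mitochondrially encoded genes, IR left 5 higher and 6 lower (5 and 6 adjusted over the list alone) in control cells. Mitochondrially encoded genes were 6 higher and 4 lower (6 and 4 adjusted over the list alone; 1 and 15 corrected) with IR in sgRnf19a cells. Mitochondrially encoded genes had 0 higher and 0 lower (0 and 1 adjusted over the list alone) in their response to IR in sgRnf19a against control cells.

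Of 12 tested fibroblast markers, IR left 1 higher and 1 lower (0 and 1 adjusted over the list alone) in control cells. Fibroblast markers were 1 higher and 0 lower (0 and 0 adjusted over the list alone) with IR in sgRnf19a cells. Fibroblast markers were 2 higher and 2 lower (2 and 2 adjusted over the list alone) with the guide in IR-treated cells. Fibroblast markers had 0 higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.0248, adjusted p = 0.633 with an estimated correlation) in their response to IR in sgRnf19a against control cells. Of 9 tested immune cell markers, IR left 0 higher and 4 lower (0 and 4 adjusted over the list alone) in control cells. Immune cell markers were 0 higher and 1 lower (0 and 1 adjusted over the list alone) with IR in sgRnf19a cells. Immune cell markers were 0 higher and 0 lower (0 and 0 adjusted over the list alone) with the guide in untreated cells. Immune cell markers were 1 higher and 0 lower (1 and 0 adjusted over the list alone) with the guide in IR-treated cells. Immune cell markers had 0 higher and 0 lower (0 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells. Of 8 tested endothelial and keratinocyte markers, IR left 1 higher and 0 lower (1 and 0 adjusted over the list alone) in control cells. These markers were 0 higher and 0 lower (0 and 0 adjusted over the list alone) with IR in sgRnf19a cells. They were 0 higher and 0 lower (0 and 3 adjusted over the list alone) with the guide in untreated cells. There the list had camera adjusted p = 0.0324, adjusted p = 0.387 with an estimated correlation. They were 1 higher and 3 lower (1 and 3 adjusted over the list alone) with the guide in IR-treated cells. They had 0 higher and 0 lower (0 and 0 adjusted over the list alone) for the difference between IR responses. Krt8 was 2.57-fold lower with the guide in IR-treated cells.

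Of 40 tested NF-kB targets, the guide left 3 higher and 1 lower (3 and 1 adjusted over the list alone; 6 and 1 corrected) in untreated cells. NF-kB targets were 17 higher and 9 lower (17 and 11 adjusted over the list alone) with the guide in IR-treated cells. NF-kB targets had 4 higher and 0 lower (10 and 2 adjusted over the list alone; 3 and 3 corrected) in their response to IR in sgRnf19a against control cells. Of 33 tested MAPK pathway genes, the guide left 1 higher and 1 lower (2 and 3 adjusted over the list alone; 5 and 5 corrected) in untreated cells. Of 40 tested mitosis genes, the guide left 0 higher and 1 lower (0 and 0 adjusted over the list alone) in untreated cells. Mitosis genes were 21 higher and 8 lower (24 and 11 adjusted over the list alone) with the guide in IR-treated cells. Mitosis genes had 0 higher and 0 lower (12 and 1 adjusted over the list alone) in their response to IR in sgRnf19a against control cells. Of 36 tested DNA repair genes, the guide left 0 higher and 2 lower (0 and 2 adjusted over the list alone) in untreated cells. DNA repair genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.754 with an estimated correlation) in their response to IR in sgRnf19a against control cells. Of 59 tested histone genes, the guide left 1 higher and 0 lower (0 and 0 adjusted over the list alone) in untreated cells. Histone genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.0133, adjusted p = 0.680 with an estimated correlation) in their response to IR in sgRnf19a against control cells. Between IR responses, the 85 ribosomal protein and 34 respiratory chain genes had 0 higher and 0 lower (0 and 0 adjusted over each list alone). Of 31 tested proteasome genes, the guide left 1 higher and 0 lower (1 and 0 adjusted over the list alone) in untreated cells. Proteasome genes were 5 higher and 0 lower (4 and 0 adjusted over the list alone; 8 and 5 corrected) with the guide in IR-treated cells. Proteasome genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells. Of 39 tested p53 target genes, the guide left 17 higher and 4 lower (18 and 4 adjusted over the list alone) in IR-treated cells. P53 target genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells. Of 39 tested extracellular matrix genes, IR left 3 higher and 15 lower (3 and 15 adjusted over the list alone; 5 and 9 corrected) in control cells. Matrix genes were 4 higher and 8 lower (4 and 8 adjusted over the list alone, 10 and 4 corrected) with IR in sgRnf19a cells. Matrix genes were 6 higher and 11 lower (6 and 12 adjusted over the list alone) with the guide in IR-treated cells. Matrix genes had 0 higher and 0 lower (4 and 1 adjusted over the list alone) for the difference between IR responses. Of 27 tested cholesterol synthesis genes, the guide left 0 higher and 1 lower (0 and 1 adjusted over the list alone) in untreated cells. Cholesterol synthesis genes had 0 higher and 0 lower (0 and 0 adjusted over the list alone) in their response to IR in sgRnf19a against control cells.

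The larger side changed with the scaling for several of these lists, so their direction is left open. With FPKM values the higher and lower counts for IR in control cells became 9 and 19 for DNA replication, 8 and 12 for nucleic acid sensing and 3 and 17 for lysosome and autophagy genes, and DESeq2 size factors gave 13 and 14 for DNA replication. For IR in sgRnf19a cells they became 5 and 16 for DNA replication, 3 and 17 for hypoxia, 3 and 7 for checkpoint, 6 and 15 for stress response, 3 and 18 for lysosome and 3 and 16 for mitochondrially encoded genes. After the length and GC correction, ubiquitin genes became 13 and 12 in control and 14 and 9 in sgRnf19a cells with IR, and extracellular matrix genes 10 and 4 in sgRnf19a cells with IR. It also gave 9 and 12 for lysosome, 7 and 4 for mitochondrially encoded and 0 and 1 for endothelial and keratinocyte genes in control cells with IR, and 6 and 8 for hypoxia and 1 and 15 for mitochondrially encoded genes in sgRnf19a cells with IR. Upper-quartile scaling gave 9 and 7 for hypoxia, 8 and 5 for mitochondrially encoded and 14 and 12 for ubiquitin genes in control cells with IR, and 11 and 8 for ubiquitin genes in sgRnf19a cells with IR. With the guide in IR-treated cells, hypoxia genes turned to 4 and 10 with it, 4 and 6 with FPKM values and 5 and 7 after the length and GC correction, and lysosome genes to 4 and 5 with it.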
